A study of Mus musculus with 10 samples.

How the data were processed

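Total RNA of wild-type NIH3T3 mouse fibroblasts, treated with DNase and depleted of ribosomal RNA, was sequenced as paired-end, strand-specific libraries, per the labels' protocols. There are 10 samples, 5 times (0, 1, 3, 6 and 9 h) in each of 2 courses, from 38 to 33 °C and from 33 to 38 °C, with 1 sample per time. The label of 1 sample has a mistyped temperature in its title, and its description puts it in the course from 33 to 38 °C. Reads were aligned to mm10 with STAR and handled with bedtools, per the submitters' processing notes, which give no versions. The annotation release, the rule for reads shared between genes or between exons and introns, and the use of strand in counting are not given in the sources used here.

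The deposited tables hold estimated counts of reads, exon and intron columns for 38087 genes, although their names speak of RPKM. The deposited values sum to between 22403625 and 48004854 for the exon columns and between 15313374 and 25233405 for the intron columns, differ in total between columns, and 22.9% of exon values above 0 are whole within 1e-06. They were therefore treated as estimates of counts and rounded to whole numbers. The test fixed before the data were examined was limma on log2 RPKM. Because the unit is a count, the edgeR quasi-likelihood test took its place, and limma on log2 RPKM, as first planned, was kept as an alternative. RPKM was computed here from the counts and the gene lengths of GENCODE M21 (GRCm38), in which 36308 of the genes (95.3%) were found by their identifiers. Coordinates and overlaps with other genes come from the same annotation.

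Every sample has 2 complete columns for exons and for introns, named by numbered series, 5 and 11 in the course from 38 to 33 °C and 2 and 13 in the other, and a further series 10 covers 1 and 3 h of the course from 38 to 33 °C. Of the 22 exon columns none lacks a sample. The 2 columns of a sample differed by more than counting noise (chi-square over degrees of freedom of 105 to 377, correlation of log2 values 0.929 to 0.968). The per-gene differences between the 2 columns of a sample correlated between samples, by 0.778 to 0.936 across genes within a course (20 pairs of samples) and 0.403 to 0.661 between courses (25 pairs), and the first principal component (46.5% of variance) separated series 2 and 5 from series 10, 11 and 13. Series 2 with 5 and series 11 with 13 each make a complete set of both courses, and were treated as a batch found in the data. The second component (18.8%) separated series 13 from series 11, so a pair is not uniform. Each series lies in 1 course only, so a difference between the series of a pair cannot be told from one between courses. The 2 columns were summed and counted as 1 sample, with a per-gene offset for the mix of series, and series 10 entered only an alternative. Nothing in the labels says whether the columns are separate cultures.

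For exon and for intron reads a negative binomial model was fitted in edgeR 4.0.16 (R 4.3.3) with TMM scaling, with an intercept and a slope on log2(h + 1) for each course. The fitted change from 0 to 9 h is the slope times the log2 of 10, and is given with a standard error. This error was derived from the test, as the absolute change over the square root of the quasi-likelihood F statistic. Contrasts were each course alone, their difference (downshift minus upshift) and their mean. The exon-to-intron ratio was tested as the interaction of read type and slope, on the TMM scale of the exon reads. Each time has 1 sample, so the residual spread holds biological scatter, technical scatter and lack of fit to a straight line together. Genes with a mean exon RPKM of at least 1 were tested (9437), and for introns and ratios also a mean intron RPKM of at least 0.05 (8757). P-values were adjusted after Benjamini and Hochberg and called at 0.05.

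Gene lists, 33 in number, were fixed before the data were examined, 5 of them markers of other cell types. The 28 with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. No list call of any measure or contrast held in camera with an estimated correlation. Fry tests a list against no change and not against other genes. The genes named were also fixed by rule: Cirbp and Rbm3, the 10 genes per direction with the largest difference between the shifts on exons among called genes that moved in opposite directions, the 5 per direction for the other contrasts, for the first hour and for 0 h, and up to 4 members per list with the largest difference. Comparisons at 1 h and 0 h used log2 RPKM with a pseudocount of 0.1 for exons and 0.01 for introns, a threshold of 2-fold, and no test. List medians in these comparisons were set against 10000 random lists matched on mean expression. Genes of the random lists were drawn independently, while members of a list can move together. The percentiles are therefore descriptive and not a test of a change.

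The exon and ratio models were tested on simulated counts with known changes. Of the changed genes with log2 changes of 0.5, 1 and 2 in the difference between shifts, the exon model (9437 genes) recovered 29.9, 98.5 and 100%, and called 0.0866% of unchanged genes. The ratio model (8757 genes) recovered 16.4, 52.2 and 100%, and called 0.631% of unchanged genes. At this depth, differences near 0.5 were mostly missed, and p-values measure only scatter between these samples, which may be technical.

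Alternatives were other scaling (library totals, RLE, median centring, separate scaling of exons and introns), DESeq2 1.42.0, limma on log2 RPKM with 3 pseudocounts, other filters, linear time, a step from 0 h to 3, 6 and 9 h, the time point as a block, each course alone, no abundance trend, other uses of the columns, and leaving out each sample. The step leaves out 1 h and sets the 1 sample at 0 h of each course against those at 3, 6 and 9 h. Its spread therefore comes from the later samples only. The order of the times within each course was also drawn at random 40 times. Sequence-level analysis of single introns was not made, since the tables give 1 intron value per gene.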

Results

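Total RNA from wild-type NIH3T3 cells, a mouse fibroblast line, was sequenced during 2 temperature courses. Cells seeded at 37 °C for 4 h were kept for 16 h at 38 °C or at 33 °C and then moved to the other temperature. Samples were taken 0, 1, 3, 6 and 9 h after the move, which gives 10 samples, with 1 sample per time in each course. The move from 38 to 33 °C is called the downshift and the move from 33 to 38 °C the upshift. For every gene, reads in exons and reads in introns were counted separately. Every sample has 2 complete columns of counts from numbered column series, 5 and 11 for the downshift and 2 and 13 for the upshift, and the labels do not say what these numbers stand for. Each column held between 22403625 and 48004854 exon reads and between 15313374 and 25233405 intron reads. The 2 columns of a sample were added and counted as 1 sample. In a principal component analysis of the columns, the component with the most variance (46.5%) separated series 2 and 5 from series 10, 11 and 13, so each comparison was also made within series 2 and 5 and within series 11 and 13.

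The series title asks how temperature acts on the splicing efficiency of Cirbp, which codes for an RNA-binding protein induced by cold. Cirbp (ENSMUSG00000045193, GRCm38 chromosome 10, 80165985 to 80172786, plus strand; 2604 bases of exon and 4198 of intron) rose after the downshift and fell after the upshift. Its exon reads went from 4.41 to 64.9 CPM (counts scaled by library size) over the 9 h of the downshift, and from 83.1 to 8.97 CPM over those of the upshift. Its intron reads, also scaled by the library size of the exon reads, went from 4.94 to 9.08 CPM and from 9.134 to 5.53 CPM. The ratio of Cirbp exon reads to intron reads therefore went from 0.893 to 7.14 after the downshift and from 9.10 to 1.62 after the upshift.

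The fitted Cirbp exon change from 0 to 9 h was 3.61 ± 0.43 on the log2 scale (SE) after the downshift and -3.72 ± 0.40 after the upshift (edgeR quasi-likelihood test, adjusted p = 0.00163 and 0.000425). The difference between the shifts, downshift minus upshift, was 7.33 ± 0.59 (adjusted p = 7.95e-05), and 7.57 within series 2 and 5 and 7.12 within series 11 and 13. For Cirbp intron reads the same difference was 1.64 ± 0.35 (adjusted p = 0.0240). The exon-to-intron ratio of Cirbp changed by 3.09 ± 0.42 after the downshift and by -2.97 ± 0.41 after the upshift (adjusted p = 0.00760 and 0.00810). The ratio difference between the shifts was 6.06 ± 0.58 (adjusted p = 0.000299), with 5.99 within series 2 and 5 and 6.12 within series 11 and 13. The Cirbp intron call was lost within series 11 and 13 (1.28, adjusted p = 0.0891), with the time point as a block (1.65, adjusted p = 0.132), with time in linear hours (1.42, adjusted p = 0.108) and without any one of 5 samples. These were the downshift samples at 0, 6 and 9 h (1.22, 1.70 and 1.55) and the upshift samples at 0 and 6 h (1.16 and 1.56).

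Rbm3 (ENSMUSG00000031167, chromosome X, 8138975 to 8145880, minus strand), which codes for another cold-inducible RNA-binding protein, rose by 1.37 ± 0.18 after the downshift and fell by 0.94 ± 0.19 after the upshift (adjusted p = 0.00182 and 0.00463; after the upshift within series 2 and 5, -0.69 with adjusted p = 0.113). Rbm3 exon reads went from 64.5 to 178 CPM and from 255 to 138 CPM, and the difference between the shifts was 2.31 ± 0.26 (adjusted p = 0.000192). Its exon-to-intron ratio differed between the shifts by 3.125 ± 0.29 (adjusted p = 0.000299), while its intron difference was -0.46 ± 0.42 (adjusted p = 0.524). The antisense gene Rbm3os overlaps Rbm3, and the counting rule for overlapping genes is not given in the sources used here. Of the 10 measured genes in the list of cold-inducible RNA-binding and cold-shock-domain proteins, 3 went up toward 33 °C and 2 went down, with the same counts adjusted over the list alone except that 4 went up (camera adjusted p = 0.637). The list passed fry, which tests against no change (adjusted p = 0.000744), with a mean difference of 0.88 and a median of -0.11. Besides Cirbp and Rbm3, Rbmx differed by 1.00 and Rbm5 by -0.77.

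**Figure D1:**
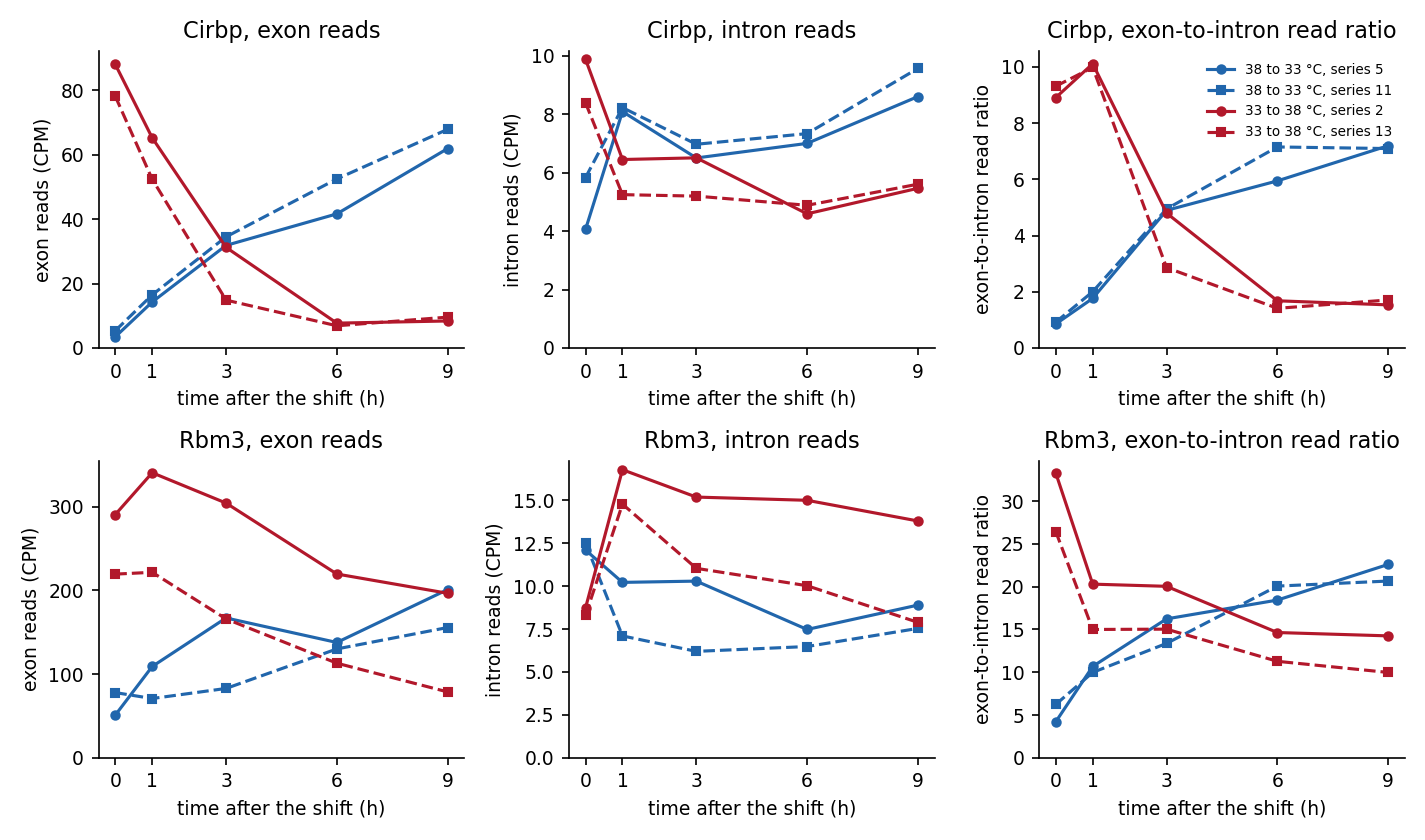
Exon reads (CPM), intron reads (CPM) and exon-to-intron read ratio of Cirbp (top) and Rbm3 (bottom) against the time after the shift (h), with 1 point per column of counts, blue for 38 to 33 °C and red for 33 to 38 °C, circles for series 5 and 2 and squares for series 11 and 13. Mean Cirbp exon reads went from 4.41 to 64.9 CPM after the downshift and from 83.1 to 8.97 CPM after the upshift, while mean Cirbp intron reads stayed between 4.74 and 9.134 CPM. Intron CPM was scaled by the library size of the exon reads.

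Across the genome, the shifts asked which mature transcripts follow temperature in opposite directions. Among 9437 genes tested on exon reads, 2260 went up toward 33 °C (higher after the downshift relative to the upshift) and 2203 went down, 4463 in all. After the downshift alone 1542 rose and 1549 fell, and after the upshift alone 1597 rose and 1643 fell. Of 1689 genes called after both shifts, 1612 moved in opposite directions and 77 in the same direction. Of these, 771 rose after the downshift and fell after the upshift, where independent lists would share 268, and 841 did the reverse, where 262 would be shared. The fitted changes of the shifts had a correlation of -0.58 across genes, which are not independent replicates. Within series 2 and 5 and within series 11 and 13, 3649 genes were called in each, of which 1231 went up and 1150 went down in both, against 375 and 330 for independent lists. Each time has 1 sample per course, so p-values measure scatter around a straight line in log2 time and not the spread between replicate cultures. Without its 0, 6 or 9 h sample the downshift called 1540, 1932 and 1645 genes, without its 0 or 6 h sample the upshift called 1821 and 2098, and comparing 0 h with 3, 6 and 9 h as a step called 299, 544 and 2348 genes for the downshift, the upshift and their difference.

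After Cirbp, the genes that went up most toward 33 °C were Cela1, an elastase-type serine protease (5.19 ± 0.28), and Thbs1, the matrix protein thrombospondin-1 (3.80 ± 0.35). They were followed by the chemokine Cxcl5 (3.38 ± 0.43), the linker histone Hist1h1d (3.30 ± 0.27), the scavenger receptor family member Scara3 (3.204 ± 0.56), the thioredoxin reductase Txnrd3 (3.09 ± 0.36), the core histone Hist4h4 (3.07 ± 0.36), the linker histone Hist1h1c (2.98 ± 0.38) and the acyl-CoA synthetase Acsbg1 (2.97 ± 0.34). Cela1 rose by 2.51 after the downshift and fell by 2.68 after the upshift. The genes that went down most were the microRNA gene Mir1953 (-3.89 ± 0.67), the spindle and centriole protein gene Spice1 (-3.73 ± 0.42), the pseudogene Gm7910 (-3.63 ± 0.20), the lectin gene Lman2l (-3.44 ± 0.30) and the DNA helicase Pif1 (-3.35 ± 0.39). Next came 1190005F20Rik (-3.34 ± 0.51), Thap2 (-3.31 ± 0.49), C330018D20Rik (-3.28 ± 0.51), L3mbtl3 (-3.22 ± 0.28) and Parpbp (-3.16 ± 0.24). All 20 had an adjusted p below 0.05, the highest being 0.00140 for Scara3. Thbs1, Lman2l, 1190005F20Rik and Parpbp overlap other genes, Mir1953 is annotated as a microRNA, and how reads shared by the pseudogene Gm7910 and other copies were counted is not given in the sources used here. Gm7910 was not called within series 11 and 13 (-1.78, adjusted p = 0.0669), and under the step comparison the calls of Cxcl5 (2.13, adjusted p = 0.0632), Hist4h4 (2.07, adjusted p = 0.0551), Hist1h1c (1.93, adjusted p = 0.0899) and Mir1953 (-2.54, adjusted p = 0.0729) were lost.

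For single shifts, the largest rises after the downshift besides Cirbp, Cela1 and Scara3 (1.92) were Spata24 (1.78) and Scara5 (1.71). The largest falls were Lars2 (-3.36 ± 1.132, with 773 CPM in series 11 against 34.9 CPM in series 5 at 0 h), Mir1953 (-2.60), the clock repressor Nr1d1 (-2.44), the microRNA gene AC087541.1 (-2.41) and the class I-like gene H2-M9 (-2.38). After the upshift the largest rises were Nfil3, a circadian repressor (2.35), Gm7910 (2.10), Lman2l (2.04), L3mbtl3 (1.9995) and Prl2c3 (1.89). The largest falls besides Cirbp and Cela1 were H2-M1 (-2.63), H2-M9 (-2.54) and Cyr61, a secreted matricellular protein (-2.45). H2-M9 and Gm7910 were measured almost only in series 2 and 5. At 0 h of the downshift H2-M9 had 21.6 CPM in series 5 and no read in series 11, and Gm7910 had 22.4 and 0.228 CPM.

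**Figure D2:**
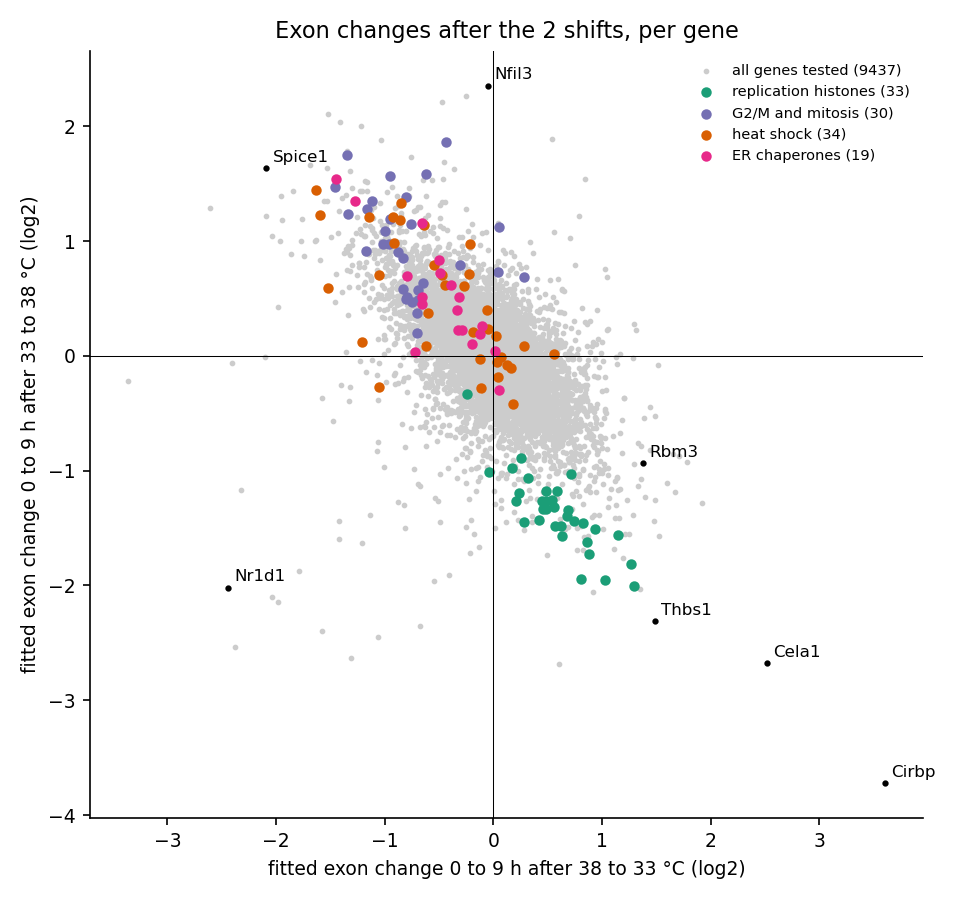
Fitted log2 change of exon reads from 0 to 9 h after 38 to 33 °C (horizontal axis) and after 33 to 38 °C (vertical axis), with 1 grey point for each of the 9437 genes tested and colours for 4 lists fixed in advance. Cirbp lies at 3.61 and -3.72, most mitosis genes (purple) lie at the upper left and most replication histones (green) at the lower right.

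Genes of the heat shock response, which code for cytosolic chaperones under the heat shock factor HSF1, went down toward 33 °C. Of 34 measured, 18 went down and 1 went up (18 and 2 adjusted over the list alone), with a median of -0.91. Examples are Chordc1 (-3.08), Hsph1 (-2.83), Ahsa2 (-2.36) and the chaperone Hsp90aa1 (-2.18). The camera test against other genes gave an adjusted p of 0.000527, and adjusted p = 0.795 with an estimated correlation. After the upshift alone 14 rose and 0 fell, and after the downshift alone 12 fell and 2 rose. The medians were -0.85 within series 2 and 5 and -0.67 within series 11 and 13.

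Chaperones and folding enzymes of the endoplasmic reticulum, the targets of the unfolded protein response, moved the same way. Of 19 measured, 12 went down and 1 went up (13 and 1 adjusted over the list alone), with a median of -0.82 (camera adjusted p = 4.20e-05, and adjusted p = 0.795 with an estimated correlation). Creld2 differed by -2.99, Sdf2l1 by -2.62, Pdia4 by -1.81 and Hyou1 by -1.49. Within series 2 and 5 and within series 11 and 13 the medians were -0.96 and -0.75.

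**Figure D3:**
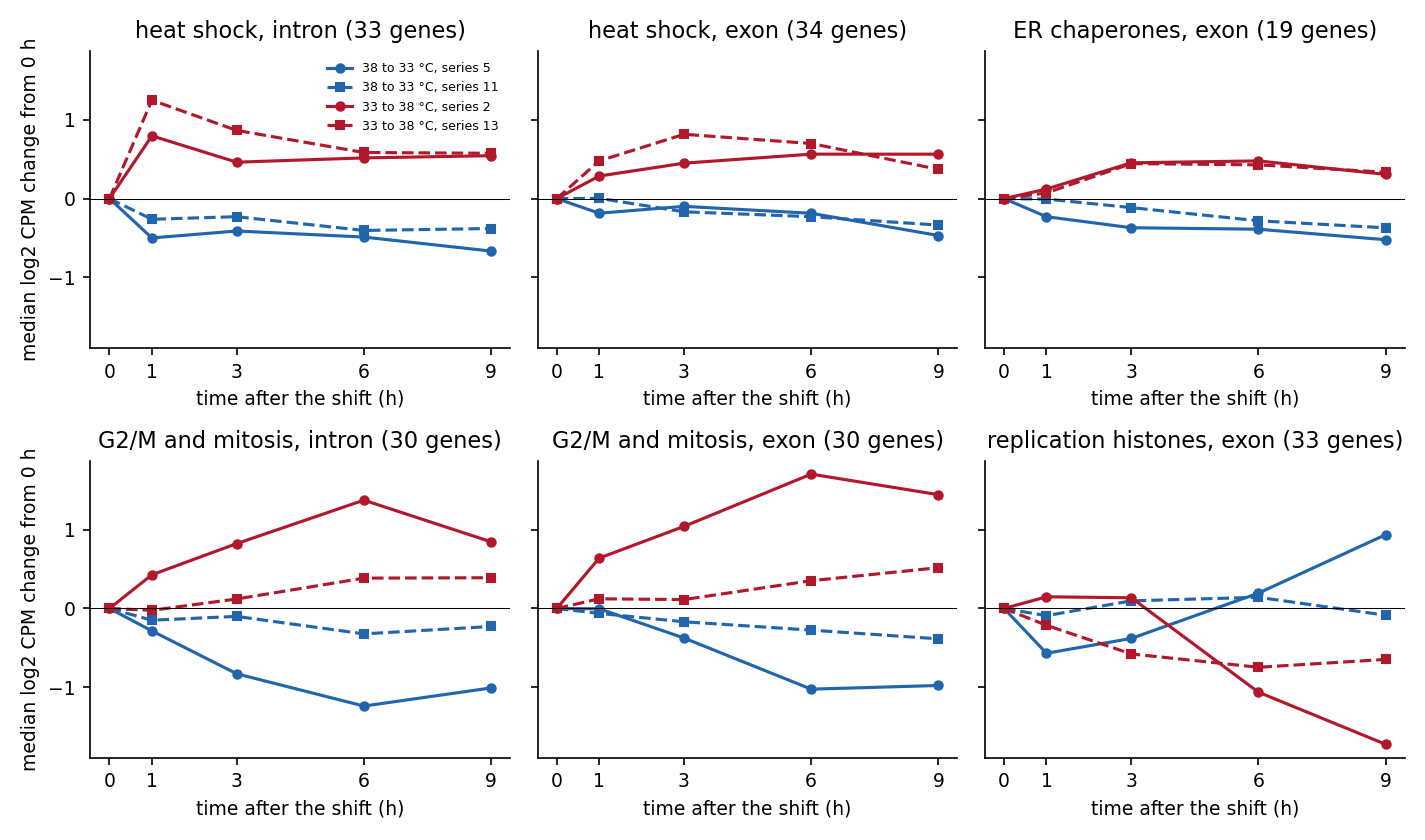
Median log2 change of CPM from 0 h (vertical axis) against the time after the shift (h) over the genes of 4 lists, blue for 38 to 33 °C and red for 33 to 38 °C, circles for series 5 and 2 and squares for series 11 and 13. The intron median of the heat shock list stood at 0.80 and 1.25 at 1 h after the upshift, and the mitosis and histone medians moved further in series 2 and 5 than in series 11 and 13. Intron CPM was scaled by the library size of the exon reads.

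Genes of G2 phase and mitosis went down toward 33 °C, and replication-dependent histones, which are made in S phase, went up. Of 30 mitosis genes 29 went down and 0 went up (30 and 0 adjusted over the list alone), with a median of -1.85 (camera adjusted p = 2.16e-13, and adjusted p = 0.708 with an estimated correlation). The largest differences were Cenpf (-3.10), the kinase Aurka (-2.93), Ube2c (-2.57) and Hmmr (-2.52). Of 33 histone genes 30 went up and 0 went down (31 and 0 adjusted over the list alone), with a median of 1.85 (camera adjusted p = 1.17e-08, and adjusted p = 0.795 with an estimated correlation). After the upshift alone 30 histone genes fell and 0 rose (median -1.34). After the downshift alone 8 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.57), so most of the difference came from the upshift. Hist1h1d, Hist4h4, Hist1h1c and Hist1h1e (2.75) led the list, and near-identical histone copies can share reads. The mitosis median was -2.59 within series 2 and 5 and -0.81 within series 11 and 13, and the histone medians were 2.51 and 0.78. Genes of G1/S and DNA replication did not pass as a list (7 up and 1 down of 29, the same adjusted over the list alone, camera adjusted p = 0.237, but median 0.51 with adjusted p = 0.000736 within series 2 and 5), with Ccne1 (1.80), Chaf1b (1.59) and Mcm6 (1.40) among the larger differences.

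Targets of the oxidative stress factor NRF2 went up toward 33 °C. Of 17 measured, 11 went up and 1 went down (the same adjusted over the list alone), with a median of 0.55 (camera adjusted p = 0.000793, and adjusted p = 0.708 with an estimated correlation). Nqo1, a quinone reductase, differed by 2.74, Tkt by 1.05, Gsr by 1.03 and Hmox1, which degrades heme, by -1.05. Fibroblast matrix genes had a higher change after the downshift than after the upshift in 12 of 23, with 1 lower (the same adjusted over the list alone) and a median of 0.39 (camera adjusted p = 0.000793, and adjusted p = 0.703 with an estimated correlation). After the downshift itself 9 of them fell and 3 rose (median -0.06, camera adjusted p = 0.391), and after the upshift 17 fell and 0 rose. Thbs1, the fibrillin Fbn1 (1.31), Timp3 (0.84) and Loxl1 (0.77) led this list. Cytosolic ribosomal proteins went up by little, 26 of 77 with 1 down (19 and 1 adjusted over the list alone) and a median of 0.18 (camera adjusted p = 0.000360, and adjusted p = 0.914 with an estimated correlation). Targets of p53 went down, 9 of 17 with 1 up (the same adjusted over the list alone) and a median of -0.97 (camera adjusted p = 0.0153, and adjusted p = 0.795 with an estimated correlation). Eda2r differed by -1.56, Ccng1 by -1.43 and Aen by -1.41, and Fas stood at -1.56 without passing. Within series 11 and 13 the p53 list did not pass (adjusted p = 0.0509).

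Some lists moved in 1 course or moved alike in both, and the camera values here belong to single shifts. Cholesterol synthesis genes rose after the downshift (7 up and 0 down of 23, median 0.28, adjusted p = 0.00248) and after the upshift (11 up and 0 down, median 0.39, adjusted p = 5.07e-06). Their difference between the shifts did not pass (3 up and 4 down, adjusted p = 0.479), with Dhcr7 at -1.12 and Lss at 0.77. With an estimated correlation the 2 calls for single shifts were lost (adjusted p = 0.881 and 0.621). Within series 11 and 13 the cholesterol list did not pass after the downshift (adjusted p = 0.446). Serum response factor targets of the actin cytoskeleton fell after the upshift (10 down and 0 up of 18, median -0.40, adjusted p = 0.000150, and adjusted p = 0.621 with an estimated correlation). After the downshift 5 of these targets also fell and 0 rose, without passing as a list (median -0.22, adjusted p = 0.0573). Their difference between the shifts did not pass (4 up and 0 down, adjusted p = 0.355), with Zyx at 0.97 and Tpm1 at 0.80. Matrix genes fell after the upshift (17 down and 0 up of 23, adjusted p = 6.98e-09, and adjusted p = 0.0694 with an estimated correlation). Ribosomal proteins rose after the downshift (54 up and 0 down of 77, median 0.19, adjusted p = 6.39e-12, and adjusted p = 0.714 with an estimated correlation). After the upshift, immediate early genes fell in the fit over 9 h (8 down and 1 up of 24, median -0.58, adjusted p = 0.00320, and adjusted p = 0.621 with an estimated correlation). At 1 h after the upshift their exon median stood 0.12 above 0 h. After the downshift, genes of hypoxia and glycolysis (11 up and 2 down of 23, adjusted p = 0.00339) and fatty acid synthesis (6 up and 0 down of 17, adjusted p = 0.0186) rose, with adjusted p of 0.714 and 0.714 with an estimated correlation. Oxidative phosphorylation passed camera (adjusted p = 0.0326, and adjusted p = 0.881 with an estimated correlation) with 7 up and 2 down of 53 (3 and 2 adjusted over the list alone). None of these 3 passed within series 11 and 13 (adjusted p = 0.356, 0.351 and 0.762).

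The other lists did not pass the camera test for the difference between the shifts, and their counts are given as up and down among all genes, with those adjusted over the list alone in brackets. Within series 2 and 5 alone, the lists of hypoxia and glycolysis (median 0.72, adjusted p = 0.00148), interferon response (-1.24, adjusted p = 0.0409), serum response factor targets (0.37, adjusted p = 0.0366) and ribosome biogenesis (0.35, adjusted p = 0.0459) did pass, and within series 11 and 13 alone oxidative phosphorylation did (0.23, adjusted p = 0.0453). Immediate early genes had 6 and 2 of 24 (4 and 1; adjusted p = 0.158), with Nr4a1 at 2.30 and Egr1, not called, at 3.29. Glycolysis and hypoxia genes had 9 and 3 of 23 (9 and 3; adjusted p = 0.159), with Pdk1 at 1.53 and P4ha1 at -1.49. Interferon response genes had 0 and 3 of 6 (0 and 3; adjusted p = 0.313), with Irf1 at -1.27 and Stat2 at -1.22. NF-κB targets had 3 and 1 of 12 (3 and 1; adjusted p = 0.369), led by Cxcl5 and Cxcl1 (1.95). TGF-β targets had 4 and 1 of 13 (4 and 1; adjusted p = 0.375), with Tgfbi at 1.33. Circadian clock genes had 0 and 3 of 16 (0 and 2; adjusted p = 0.523), with Nfil3 at -2.40 and Per2 at -2.01. Genes of the ATF4 stress response had 2 and 4 of 20 (2 and 4; adjusted p = 0.517), with Atf5 at -1.17. Fatty acid synthesis genes had 6 and 4 of 17 (6 and 4; adjusted p = 0.614), with Acsl4 at 1.39.

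Genes of RNA processing went both ways. The SR splicing factors had 4 up and 4 down of 21 (the same adjusted over the list alone; adjusted p = 0.710), with Srsf5 at 1.56, Tra2a at -1.69 and Srsf7 at -1.37. The hnRNP proteins had 11 up and 8 down of 28 (the same adjusted over the list alone; adjusted p = 0.637), with Hnrnpdl at 1.58, Hnrnpd at 1.40 and Hnrnph3 at -1.32. The core spliceosome had 5 up and 9 down of 42 (4 and 8 adjusted over the list alone; adjusted p = 0.781), with Snrpa at -1.37 and Prpf3 at -1.08. The kinases of the CLK, DYRK and SRPK families had 3 up and 1 down of 10 (the same adjusted over the list alone; adjusted p = 0.523), with Dyrk3 at -1.13 and Dyrk1a at 0.76. Nonsense-mediated decay factors had 2 up and 2 down of 14 (the same adjusted over the list alone; adjusted p = 0.873). Hosts of small nucleolar RNAs and nuclear long noncoding RNAs had 1 up and 1 down of 6 (0 and 0 adjusted over the list alone; adjusted p = 0.856). Ribosome biogenesis genes had 7 up and 3 down of 40 (5 and 3 adjusted over the list alone; adjusted p = 0.523), and oxidative phosphorylation genes had 9 up and 6 down of 53 (7 and 5 adjusted over the list alone; adjusted p = 0.517).

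Most markers of other cell types were low. Median exon RPKM was 0.00348 for adipocyte, 0.00153 for epithelial, 0.00813 for macrophage and leukocyte, 0.0160 for endothelial and 0.0222 for muscle markers, and the highest single markers had 6.16, 15.2, 6.04, 0.504 and 1.39 RPKM in the same order. Only 5 of these markers were tested, and Lpl (0.10), Krt14 (0.17), Cd14 (-0.29), Lyz2 (0.09) and Acta1 (0.06) were not called for the difference between the shifts.

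Changes that both courses share were asked as the mean of the 2 shifts. For exon reads 139 genes rose and 195 fell. Of 41 orders of the times, the real one included, 3 gave as many calls and the highest other gave 2823. An order that runs 1 course backward would turn opposite changes into shared ones, so these orders cannot decide on chance, which is left open. With a step from 0 h to 3, 6 and 9 h 0 genes were called in edgeR (539 at unadjusted p under 0.05, and 861 calls in DESeq2 without the step). The clock repressor Nr1d1 fell by 2.23 ± 0.32 (adjusted p = 0.00872; -2.31 within series 2 and 5 and -2.20 within series 11 and 13), from 95.3 to 21.6 CPM after the downshift and from 102 to 18.5 CPM after the upshift. Cry1, another clock repressor, rose by 0.87 ± 0.16 (adjusted p = 0.0200), and Nfil3 rose by 1.15. The actin genes Acta1 (-2.07 ± 0.25) and Actg2 (-2.06 ± 0.33) fell. H2-M9 (-2.46), Prl2c3 (1.21), Prl2c2 (1.19) and I830012O16Rik (0.86) were also called, and within series 11 and 13 H2-M9, Prl2c3 and Prl2c2 stood at -0.02, -0.03 and 0.01. Nr1d1 overlaps Thra, and the Prl2c genes are near-identical copies. Within series 2 and 5 there were 696 calls and within series 11 and 13 there were 36. Leaving out 1 sample moved the count to between 88, without the downshift 9 h sample, and 506, without the upshift 0 h sample.

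Intron reads, taken to come mainly from unspliced RNA, were called in fewer genes than exon reads on log2 time, while the step from 0 h to 3, 6 and 9 h called 861 on introns and 299 on exons for the downshift. Of 8757 genes tested, 312 went up toward 33 °C and 305 went down, while 42 rose and 55 fell after the downshift and 75 rose and 90 fell after the upshift. The intron counts were scaled on their own totals, and on the exon totals the difference between the shifts had 132 up and 1427 down. Within series 2 and 5 there were 666 calls and within series 11 and 13 there were 314, of which 79 went up and 77 went down in both, against 5.70 and 6.23 for independent lists. The genes that went up most were the osteocalcin gene Bglap2 (5.93 ± 1.33), Thbs1 (3.85), Cxcl5 (3.12), the cytokine receptor Il18rap (2.76 ± 0.49) and Slurp1 (2.56 ± 0.30, overlapping Them6). Those that went down most were Rnf26 (-3.26 ± 0.43), the pseudogene Gm14127 (-3.17 ± 0.72), L3mbtl3 (-3.03), the repressor Bcl6 (-2.85 ± 0.49) and Pcbd2 (-2.50 ± 0.42), of which Rnf26, Bcl6 and Pcbd2 overlap other genes. Mitosis genes went down on introns too, 19 of 30 with 0 up and a median of -1.20 (26 and 0 adjusted over the list alone; camera adjusted p = 1.58e-18, and adjusted p = 0.712 with an estimated correlation). Matrix genes (4 up and 0 down of 22; 7 and 0 adjusted over the list alone; adjusted p = 0.000420, and adjusted p = 0.712 with an estimated correlation) and NRF2 targets (2 up and 0 down of 17; the same adjusted over the list alone; adjusted p = 0.00544, and adjusted p = 0.948 with an estimated correlation) went up. With the time point as a block no intron call for the difference between the shifts was left in edgeR (1496 genes at unadjusted p under 0.05, and 1241 calls in DESeq2 without the block). Without single samples the count lay between 146, without the downshift 0 h sample, and 1008, without the upshift 1 h sample. The downshift count fell from 97 to 0 without its 6 or its 9 h sample (1262 and 1238 genes at unadjusted p under 0.05 in edgeR, and 700 calls in DESeq2 with all samples) and to 1 without its 0 or its 3 h sample, and the upshift count from 165 to 12 and 13 without its 6 or its 9 h sample.

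The exon-to-intron ratio was asked as a measure of how far precursor RNA had been turned into mature RNA. On 1 shared scale for exon and intron reads, 1695 of 8757 genes went up toward 33 °C and 248 went down, so 87.2% of the calls went up. After the downshift 274 rose and 52 fell, and after the upshift 32 rose and 518 fell. The median over all genes was 0.28 for the difference between the shifts, 0.22 within series 2 and 5 and 0.32 within series 11 and 13. When exon and intron reads were scaled separately the median was -0.02, and 560 genes went up and 551 went down, with 83 and 98 for the downshift and 67 and 100 for the upshift. The direction of most ratio calls therefore holds only relative to the shared scale, while Cirbp stood at 5.77 ± 0.59 on separate scales. After Cirbp the ratio went up most for Cela1 (4.92 ± 0.39), the histone gene Hist1h2bp (3.87 ± 0.58), 2010107H07Rik (3.58 ± 0.53, overlapping Pbrm1) and 2010012O05Rik (3.30 ± 0.50). It went down most for Bglap2 (-4.59 ± 1.33), Rmi2 (-2.87 ± 0.70), Rassf6 (-2.71 ± 0.45), 1190005F20Rik (-2.42 ± 0.48) and Ubxn2b (-2.34 ± 0.41). As a list, the mitosis genes had lower ratio changes than other genes (median -0.22, 0 up and 2 down of 30; 0 and 0 adjusted over the list alone; camera adjusted p = 6.58e-06, and adjusted p = 0.867 with an estimated correlation). With the time point as a block 317 genes were called, and without single samples the count lay between 1007, without the downshift 6 h sample, and 2214. Within series 11 and 13 there were 9, 133 and 546 calls for the downshift, the upshift and their difference, and the downshift called 6 without its 6 h sample and the upshift 13 without its 6 h sample.

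The first hour was described without a test, since 1 sample stands at each time, on log2 RPKM with a pseudocount of 0.1 for exons and 0.01 for introns. One hour after the upshift, 104 genes were at least 2-fold higher and 32 at least 2-fold lower on introns, against 18 and 15 on exons. The intron reads of the heat shock list were higher by a median of 1.08, with 17 of 33 at least 2-fold higher (0.83 in series 2 and 1.17 in series 13). This median stood above that of all 10000 random lists matched on expression (percentile 100). Genes of random lists were drawn independently, while list members move together (estimated correlation 0.49 for this list on introns after the upshift). The percentiles of the first hour are therefore descriptive and not a test. Dnajb1 (2.35), Hsph1 (2.14) and Dnaja1 (2.03), which code for chaperones and a co-chaperone family, were among the intron reads that differed most, beside Kpna1 (3.22). Yod1 (-1.86) and the transcription factor Klf11 (-1.75) were lower. On exons Hspa1b (2.26), Egr1 (1.77), Dnajb1 (1.64) and Ccdc117 (1.60) were higher. Actin cytoskeleton targets of the serum response factor (median 0.70), endoplasmic reticulum chaperones (0.61) and p53 targets (0.59) also stood at percentile 100 on introns. One hour after the downshift the differences were smaller, with 45 genes higher and 28 lower on introns and 8 and 4 on exons. The balance turned between the series, with 82 higher and 102 lower on introns and 13 and 27 on exons in series 5, and 49 and 26, and 20 and 10, in series 11. On exons the immediate early genes stood at percentile 100 after both shifts (median 0.28 after the downshift and 0.12 after the upshift). After the downshift, intron medians stood at percentile 0 for p53 targets (-0.54), heat shock (-0.40), mitosis (-0.25) and endoplasmic reticulum chaperones (-0.245). They stood at percentile 100 for G1/S (0.29) and ribosome biogenesis genes (0.24). Replication histones stood at -0.27 on exons (percentile 0), with -0.64 in series 5 and -0.03 in series 11. Egr1 (1.96) and Klf11 (1.76) were higher and Hsph1 (-1.46) and Dnajb1 (-1.42) lower on introns, and on exons Cirbp (1.71) and Ppp1r15a (1.15) were higher. The changes of the 2 column series had correlations across genes of 0.669 and 0.648 on introns and 0.449 and 0.177 on exons, for the upshift and the downshift. Lars2 on exons (-4.27 after the downshift) and Kpna1 on introns each rest on 1 column of counts. Kpna1 stood at 0.16 in series 2 and 4.27 in series 13. Dnaja1, Yod1 and Ppp1r15a overlap other genes.

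After 16 h at a constant temperature, the 0 h samples of the 2 courses compare cells kept at 33 °C with cells kept at 38 °C, again with 1 sample each and no test. At 33 °C 312 genes were at least 2-fold higher and 187 at least 2-fold lower on exons, of which 136 and 65 in both pairs of series. The 33 °C samples at 0 h come from series 2 and 13 and the 38 °C samples from series 5 and 11, so this difference cannot be separated from one between series. The balance turned between the pairs, with 387 higher and 492 lower in series 2 and 5 and 518 and 179 in series 11 and 13, and introns had 84 higher and 250 lower (74 and 739, and 160 and 260) around a median over all genes of -0.24. Ogn (4.28), Cirbp (4.14), Slurp1 (3.63), Aspn (3.59) and Nqo1 (3.19) were highest over 38 °C. Ogn and Aspn, small proteoglycans of the matrix, overlap Cenpp. Matrix genes were higher at 33 °C by a median of 0.92, with 11 of 23 at least 2-fold higher (percentile 100; 0.61 in series 2 and 5 and 1.16 in series 11 and 13). Mitosis genes stood at a median of -1.02 (percentile 0; -1.40 and -0.53) and heat shock genes at -0.59 (percentile 0; -0.47 and -0.62), with 15 of 30 and 10 of 34 at least 2-fold lower. Replication histones stood at 0.76 (percentile 100; 1.24 and 0.15). The percentiles at 0 h are descriptive too, since genes of the random lists were drawn independently. The lowest were Lars2 (-4.64, for which series 11 of the downshift had 773 CPM and series 5 had 34.9 CPM), the pseudogenes Gm7910 (-2.71) and RP23-391B20.2 (-2.52), Gm12603 (-2.30) and the long noncoding RNA AC117663.1 (-2.22). The differences after 16 h had a correlation of 0.196 across genes with those at 9 h after the shifts, and 59.2% of genes had the same sign.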

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

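The tests of the Cirbp pattern, of time since seeding, of separate scaling and of the numbered series were chosen after the results were seen. The tests on intron level, on matched random lists and on the order of the times were written before theirs were.

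The 2 courses differed in 4463 genes on exon reads, 617 on intron reads and 1943 in the exon-to-intron ratio, by the edgeR test of the difference itself. The times were put in 40 other orders within the courses. Of these 41 orders, real one included, 1 gave as many exon calls for the difference (the highest other gave 3883), 1 as many intron calls (237) and 1 as many ratio calls (1540). A chance order of the times can therefore be excluded for these at the 0.05 level, with no adjustment over the counts compared. The downshift alone had 3091 exon, 97 intron and 326 ratio calls, each reached by 1 order (highest others 2547, 34 and 64). The upshift alone had 3240 exon calls (1 order, highest other 2162) and 550 ratio calls (1 order, highest other 403). Each draw reordered both courses, which share 1 residual variance per gene. These counts therefore argue only against a random order in both courses together, and chance in 1 course alone is left open. For the 165 intron calls of the upshift 2 of 41 orders gave as many, and the other of these gave more (234). For that count chance is left open even for both courses together. These shares are for a random order and hold no block for the time point, with which the difference called 3840 genes on exons, 317 on ratios and 0 on introns in edgeR (1496 at unadjusted p under 0.05, and 1241 in DESeq2 without the block). Single samples also decide some of these counts. The intron calls of the downshift went to 0 without its 6 or its 9 h sample (1262 and 1238 at unadjusted p under 0.05, and 700 in DESeq2 with all samples) and to 1 without its 0 or its 3 h sample, and its ratio calls to 6 and 20 without its 6 or its 9 h sample. Those of the upshift went to 12 and 13 on introns and to 13 and 45 on ratios without its 6 or its 9 h sample. For the 334 exon changes shared by both courses, 3 of 41 orders gave as many and 1 of them gave 2823. An order that runs 1 course backward would turn opposite changes into shared ones. The other orders are therefore no measure of chance for shared changes, and the test cannot decide on chance, which is left open.

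The lists whose exon changes differed between the courses were the heat shock genes (median -0.91), the endoplasmic reticulum chaperones (-0.82), the ribosomal proteins (0.18), the mitosis genes (-1.85), the replication histones (1.85), the p53 targets (-0.97), the matrix genes (0.39) and the NRF2 targets (0.55). All 8 calls were lost with an estimated correlation in camera (adjusted p = 0.703 to 0.914). All 8 lists passed fry (adjusted p = 0.000396 to 0.0278), which tests a list against no change and not against other genes. The named genes with such a difference were Cirbp (7.33), Rbm3 (2.31), Cela1 (5.19), Thbs1 (3.80), Cxcl5 (3.38), Hist1h1d (3.30), Scara3 (3.204), Txnrd3 (3.09), Hist4h4 (3.07), Hist1h1c (2.98) and Acsbg1 (2.97). In the other direction they were Mir1953 (-3.89), Spice1 (-3.73), Gm7910 (-3.63), Lman2l (-3.44), Pif1 (-3.35), 1190005F20Rik (-3.34), Thap2 (-3.31), C330018D20Rik (-3.28), L3mbtl3 (-3.22) and Parpbp (-3.16). The columns of series 10, outside the comparisons, held Cirbp reads as well, 484 at 1 h and 927 at 3 h of the downshift, a log2 CPM change of 1.42 against 1.16 in series 5 and 1.07 in series 11.

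Cirbp exon reads differed between the shifts by far more than its intron reads. A change of transcription alone would move both alike, and the ratio difference of 6.06 ± 0.58 argues against it as the whole cause. A library-wide shift of exon against intron reads is argued against by the ratio difference on separate scales, 5.77 ± 0.59, and a difference between the numbered series by the smaller of the values within the pairs of series, 5.99. A temperature effect on the splicing of Cirbp may account for the pattern, as may a temperature effect on the stability of its mature RNA or of its introns. The tables give 1 intron value per gene and no rates, so these were not tested apart.

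Ratio calls mostly went up toward 33 °C. On separate scales 50.4% of the calls went up, but that scaling centres the ratios (median -0.02 against 0.28), so this value says nothing for or against one library-wide shift of exon against intron reads. Genomic DNA in the intron counts would shift genes of low intron level most, by over 0.2 more than genes of high level, but the 25% of genes with the lowest intron level lay only 0.047 above the 25% with the highest (95% interval 0.00909 to 0.0790). A changing mix of the numbered series is argued against by the smaller of the medians within the pairs of series, 0.22. Whether the shift is biological, such as slower splicing or intron decay at 38 °C in many genes, or comes from RNA or library preparation could not be told from these data, since each time has 1 sample and no external standard.

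Mitosis genes went down and replication histones went up toward 33 °C. Time since seeding, if it acted alike in both courses, would move a list the same way in both. The mitosis median was 0.95 after the upshift and -0.81 after the downshift, and the histone median was -1.34 and 0.57. These values argue only against a time effect alike in both courses. The courses spent 16 h at different temperatures before the shift and already differed at 0 h. At 33 °C over the other temperature, exon medians there were -1.02 for mitosis genes and 0.76 for histones, with 1 sample each. From different starts the same hours could move a list in opposite directions, so time since seeding is left open. Among 10000 random lists matched on exon length and expression the histone median stood at percentile 100 and the mitosis median at percentile 0, which argues against length and level. Both lists passed camera at the preset correlation of 0.01 within both pairs of series (highest adjusted p = 6.44e-07). Their medians were -2.59 and 2.51 in series 2 and 5 against -0.81 and 0.78 in series 11 and 13. The estimated correlation was 0.50 for the mitosis genes and 0.91 for the histones, and camera with it was not run within the pairs. Each series lies in 1 course only, so a difference between the series of a pair is left open. A change in the share of cells in S phase and in G2 and mitosis with temperature may account for both lists as a hypothesis, and no cell cycle measurement was analysed here.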

How the results depend on the processing

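The alternatives with DESeq2, library totals, RLE factors, other uses of the numbered series, exons and introns on other scales, and the series pairs alone were chosen after seeing the data. Limma at pseudocounts of 0.1 and 0.01 is the test planned in advance, and its use as an alternative to edgeR was chosen after seeing the data. In what follows the order is downshift, upshift and their difference, and the cause of a change was not tested unless the alternative itself names it. Of 569 alternatives for 20 single genes, 564 kept direction and call and 5 lost the call, and none changed sign. The balance of up and down calls depended on scaling. The ratio calls of the downshift went from 274 up and 52 down to 83 and 98 on separate scales. The intron calls of the upshift went from 75 up and 90 down to 343 and 53 on exon totals, to 396 and 59 in limma at pseudocounts of 0.1 and 0.01 and to 107 and 54 with library totals, and those of the difference from 312 and 305 to 132 and 1427, 140 and 1114, and 223 and 446. The exon calls of the upshift went from 1597 up and 1643 down to 1918 and 1319 with library totals. The exon and ratio differences of Cirbp kept their call under all alternatives, and without single samples lay between 6.61 and 7.94 and between 5.68 and 7.18. The block for the time point pairs the 2 courses at each of the 5 times. At this depth (up to 48004854 exon and 25233405 intron reads per column), simulated ratio differences of 0.5 were recovered in 16.4% of genes and exon differences of 0.5 in 29.9%. The simulation changed few genes at a fixed dispersion, so these shares need not hold for the real data.

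Exon counts changed as follows. The filter at 5 times the level, which tests fewer genes, gave 1858, 2011 and 2639. The step from 0 h to 3, 6 and 9 h gave 299, 544 and 2348, and 0 shared calls in edgeR (539 at unadjusted p under 0.05). Series 11 and 13 alone gave 2001 for the downshift. Shared calls were 635 with linear hours, 861 in DESeq2, 759 with 22 columns, 696 in series 2 and 5 and 36 in series 11 and 13. Without single samples the downshift gave 1540 to 3356, the upshift 1821 to 3352 and shared calls 88 to 506. The downshift gave 1540, 1932 and 1645 without its samples at 0, 6 and 9 h, and the upshift 1821 and 2098 without its samples at 0 and 6 h. Shared calls were 129, 112 and 88 without the downshift samples at 1, 6 and 9 h, and 506, 148, 183 and 93 without the upshift samples at 0, 1, 6 and 9 h. The difference lay between 3499 and 4619.

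Intron counts for the upshift and the difference were 455 and 1254 in limma at pseudocounts of 0.1 and 0.01, 453 and 1267 at 10 times larger and 458 and 1253 at 10 times smaller ones. No filter gave 370, 415 and 1280, the filter at 5 times the level 102 and 371 for the upshift and the difference, and linear hours 45 and 118 for the downshift and the difference. The step gave 861, 362 and 1926, DESeq2 700, 641 and 1241, and 22 columns with series intercepts 1244, 1056 and 1952. Scaling by exon totals gave 413, 396 and 1559. The upshift fitted alone gave 32, and the time point as a block 0 for the difference (1496 at unadjusted p under 0.05, and 1241 in DESeq2 without the block). With series 10 the downshift gave 64, and without the series 11 columns of 3 and 9 h it gave 49. Series 2 and 5 gave 547 for the upshift, and series 11 and 13 gave 13, 65 and 314. Without single samples the counts lay between 0 and 568, 12 and 426, and 146 and 1008. The downshift count of 0 came without its 6 h or its 9 h sample (1262 and 1238 at unadjusted p under 0.05, and 700 in DESeq2 with all samples). It gave 1, 36 and 1 without its samples at 0, 1 and 3 h, and 568, 254, 34 and 59 without the upshift samples at 0, 1, 3 and 6 h. The upshift gave 426 and 33 without the downshift samples at 0 and 6 h, and 402, 85, 12 and 13 without its own at 0, 3, 6 and 9 h. For the difference, the count was 146, 215 and 360 without the downshift samples at 0, 6 and 9 h, and 336, 1008, 400 and 185 without the upshift samples at 0, 1, 3 and 6 h. The Cirbp intron difference lost its call with linear hours (1.42), with the block (1.65) and in series 11 and 13 (1.28), and lay between 1.16 and 1.90 without single samples. It also lost its call without the downshift samples at 0, 6 and 9 h and without the upshift samples at 0 and 6 h.

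Ratio counts were 133 and 362 for the downshift and the upshift in limma at pseudocounts of 0.1 and 0.01, 142 and 365 at 10 times smaller ones, and 158 for the downshift at 10 times larger ones. Linear hours gave 36 and 185, DESeq2 778 and 1036, 22 columns 1446, 1743 and 3071, and separate scaling 181, 167 and 1111. The filter at 5 times the level gave 1282 and the block 317 for the difference, and the upshift fitted alone gave 122. With series 10 the downshift gave 202, without the series 11 columns of 3 and 9 h 707, and in series 2 and 5 672. Series 11 and 13 gave 9, 133 and 546. Without single samples the counts lay between 6 and 661, 13 and 800, and 1007 and 2214. The downshift gave 120, 6 and 20 without its samples at 1, 6 and 9 h, and 564, 661, 203, 110 and 198 without the upshift samples at 0, 1, 3, 6 and 9 h. The upshift gave 348 without the downshift sample at 6 h, and 257, 13 and 45 without its own at 0, 6 and 9 h. For the difference, 1007 and 1210 were called without the downshift samples at 6 and 9 h, and 1215, 1063 and 1248 without the upshift samples at 0, 6 and 9 h.

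Genes at least 2-fold apart at 1 h on exons, 12 after the downshift and 33 after the upshift, became 7 and 13 with 10 times larger pseudocounts, 210 and 202 without a filter, 3 and 10 with the filter at 5 times the level, 40 and 56 in series 2 and 5 and 30 and 58 in series 11 and 13. On introns, 73 and 136 became 34 and 84, 638 and 631, and 23 and 72 under the first 3 of these, and 184 after the downshift in series 2 and 5. The 499 genes 2-fold apart at 0 h became 258, 1150 and 234, and 879 in series 2 and 5. Of the 8 exon, 3 intron and 1 ratio lists called, 0 were called with an estimated correlation in camera. Series 2 and 5 gave 13, 10 and 3 called lists, series 11 and 13 gave 7 and 4 on introns and ratios, and fry gave 10 on ratios.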

Other observations

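The tests on intron length and on the ratio after 16 h were written before their results were seen, and the odd features below were chosen after their values were seen.

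Some genes of the molecular clock were called in 1 or both courses. Besides Nr1d1, Cry1 and Nfil3, the clock output gene Dbp fell by 2.33 after the downshift (adjusted p = 0.00943) and stood at -1.16 after the upshift (adjusted p = 0.108), and Arntl stood at 0.79 and 1.22 (adjusted p = 0.207 and 0.0599). Per2 stood at -0.62 after the downshift (adjusted p = 0.227) and rose by 1.39 after the upshift (adjusted p = 0.0179). Of the 16 clock genes tested, 1 rose and 3 fell after the downshift, and 3 rose and 1 fell after the upshift, and on exons the list passed in neither (camera adjusted p = 0.391 and 0.969). On introns it passed after the downshift, with 2 of 16 down and 0 up and a median of -0.33 (camera adjusted p = 0.00186, and adjusted p = 0.482 with an estimated correlation), and not after the upshift (adjusted p = 0.7995). Dbp and Arntl were chosen after their values were seen.

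In the hypoxia and glycolysis list, members went apart. The collagen prolyl hydroxylases P4ha1 and P4ha2 differed between the shifts by -1.49 and -1.38, while Pdk1, which inhibits pyruvate dehydrogenase, differed by 1.53 and the mitophagy gene Bnip3 by 1.01.

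Longer introns may be spliced with a delay that depends more on temperature. The Spearman correlation across genes of the ratio difference and the total intron length was 0.153, between the bounds of 0.1 and 0.3 set in advance, so the test leaves it open. The median ratio difference went from 0.17 in the 25% of genes with the shortest introns (median 3069 bases) through 0.24 and 0.32 to 0.39 in the 25% with the longest (84665 bases).

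If temperature itself sets the exon-to-intron ratio, ratio differences may last at a constant temperature. Across genes, the log2 ratio difference of cells kept for 16 h at 33 °C over 38 °C had a correlation of 0.387 with that 9 h after the shifts, above the bound of 0.3 set in advance. The medians were 0.27 and -0.06, and 51.4% of genes had the same sign. Cirbp stood at 3.24 after 16 h and 2.09 at 9 h, and Rbm3 at 2.50 and 0.76. The difference after 16 h is of series 2 and 13 over series 5 and 11, and the difference at 9 h is of series 5 and 11 over series 2 and 13. The samples at 0 h also enter the shift courses, but not the 9 h differences.

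Single features took an unusual share of reads in some columns. AY036118 held 1.68% of exon reads and 3.80% of intron reads in series 11 at 9 h of the downshift, where the median over columns was 0.00791% and 0.0221%, and 0.576% of intron reads in series 13 at 1 h of the upshift. In series 11 at 9 h of the downshift Kpna1 held 0.774%, Fgfr2 0.305% and Zc3h7a 0.304% of intron reads. Lars2 had 773 exon CPM in series 11 at 0 h of the downshift, 84.3 CPM there at 9 h and at most 34.9 CPM in every other column of the complete series. H2-M9, H2-M1 and Gm7910 had reads mainly in series 2 and 5. At 0 h of the upshift H2-M1 had 4.26 CPM in series 2 and 0.190 CPM in series 13, and Prl2c3 had 26.3 and 2.10 CPM.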
